A study of Homo sapiens with 18 samples.

How the data were processed

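Total RNA was sequenced in 18 libraries, 3 for each of 6 groups: H460 and MCF7 cells in 2D, in 3D_FBSlow and in 3D_SM. Per the labels, libraries were made with a stranded total RNA kit that removes ribosomal RNA, 2D medium held 10% FBS, and 3D_FBSlow is a nutrient-restricted medium with 2% FBS. Per the labels, 3D_SM is a DMEM/F-12 medium with 0.5% glucose, 2.5 mM glutamine, 2% B-27, 5 µg/ml heparin, 20 µg/ml insulin, 20 ng/ml each of EGF and bFGF, and 0.1% BSA.

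The deposited tables hold 29744 genes under symbols of an older annotation. The deposited estimated counts were made by the authors with Salmon, summed to genes and are whole numbers. The deposited TPM come from the same quantification by the authors. The submitters' processing notes name the hg38 genome and DESeq2 without versions. Every fold change here was computed anew from the tables. No column of the tables was left unused. Gene positions were taken from GENCODE release 29 on GRCh38, which names 22616 of the genes.

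Library totals ranged from 11896677 to 28955463 estimated counts. Reads assigned to 28S and 45S ribosomal RNA made 0.641 to 9.57% of a library, 7SL RNA 4.24 to 9.25% and MALAT1 0.852 to 6.72%. A count of 0 in a group of 3 libraries allows up to 3 counts, which in H460 2D is 0.0585 CPM, and folds against such a group are given as bounds computed with that floor over the group. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. Values of genes with near-identical copies, such as histones, MT1 metallothioneins, HSPA1A and HSPA1B, AKR1C genes and the pseudogenes named in the report, depend on how Salmon shares reads among the copies.

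Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM scaling, robust quasi-likelihood fit, two-sided F tests, Benjamini-Hochberg FDR under 0.05). The 9 libraries of each line were fitted together with a mean per group, over 14396 genes in H460 and 14420 in MCF7. The common coefficient of biological variation was 0.122 in H460 and 0.155 in MCF7, and TMM factors ranged from 0.894 to 1.097. A fit of all 18 libraries with 6 group means tested whether a change differs between the lines, over 15856 genes (coefficient 0.142). Genes without a read in both conditions of 1 line cannot be called there: 556 for FBSlow against 2D, 548 for SM against 2D and 443 for SM against FBSlow, of which 231, 178 and 168 still have a difference of at least 2-fold. CPM, computed here from the deposited counts, use the TMM-scaled totals. Log2 fold changes are edgeR's with its default prior, and their SE were derived here from the F statistic, and left out of the gene tables where p is above 0.99. Shared genes are those called with the same sign in both media and both lines.

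Gene lists and the choices of test, filter and named genes were fixed before the data were examined. Of 772 listed genes, 724 were matched by symbol and 34 by an older symbol. The 14 not matched are 13 mitochondrially encoded genes, so that this list was not analysed here, and 1 histone gene. The 38 lists cover glycolysis, hypoxia outside glycolysis, the TCA cycle, the nuclear-encoded respiratory chain, mitochondrially encoded genes, the pentose phosphate and serine pathways, glutamine and amino acid use, cholesterol, fatty acid synthesis, fatty acid oxidation, mitosis, DNA replication, histones, cytosolic ribosomal proteins, ER stress, ATF4 targets, heat shock proteins, NRF2 targets, p53 targets, autophagy and lysosome, interferon-stimulated genes, NF-kB, mesenchymal genes, epithelial junctions, extracellular matrix and integrins, cytoskeleton with YAP and SRF targets, EGF and FGF early response, insulin and FOXO, glucocorticoid, retinoic acid and estrogen receptor targets, stem cell genes, metallothioneins, markers of fibroblasts, leukocytes and endothelium, and luminal and lung line markers. Lists with at least 3 measured members were tested with camera (preset correlation 0.01) and adjusted over 35 lists in each line and 37 in the differences. The endothelial list had fewer than 3 measured members in either line, as had the leukocyte list in H460 and the fibroblast list in MCF7. Camera was repeated with an estimated correlation, and fry tested whether a list's genes move, on balance, one way, without comparing them with other genes.

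ALDOC and ENO2 are named in each comparison. Otherwise the report names the 6 largest rises and falls of a comparison among genes with a symbol, an FDR under 0.05, a mean log2 CPM of at least 2 and replicates that do not overlap, a condition that chance alone meets in 10% of genes at 3 against 3. It also names up to 3 members with the smallest p of each list and any further member needed to show a direction. For the shared sets these are the 10 genes with the largest smallest change, and for the line differences the 5 largest each way. Genes without a standard symbol are not named.

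On simulated data built from these libraries, with known changes in 200 genes, edgeR recovered 49.3%, 77.6% and 95.5% of genes changed 1.5-fold, 2-fold and 4-fold in H460, 25.4%, 73.1% and 93.9% in MCF7, and 9%, 58.2% and 80.3% of differences between the lines. False calls made 8.6%, 7.2% and 3% of its calls, and 15.3%, 20.1% and 8.6% of those of DESeq2. With genes drawn independently, all 3 shifted lists and 0 of 32 others were called per line. Of 200 genes changed 4-fold in all 4 comparisons, 95% were recovered as shared, with 0 others. Similarity of replicates was checked by a chi-square test of each gene with a summed count of 100 to 1000 between the libraries of a pair, where sampling alone gives 5% of genes a p under 0.05, and the MCF7 2D pairs gave 7.63 to 11.3%.

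Alternatives were DESeq2 1.42.0, RLE scaling, scaling by library totals only, no filter, a filter of 50 counts in 3 libraries, other libraries in the fit, a replicate block, and limma-trend (limma 3.58.1) on log2(TPM + 1) and log2(TPM + 0.1) with a mean TPM of at least 0.5 or no filter. Each replicate was left out in turn, and a fold change of at least 2 was required. Summing replicates 1 and 2 of H460 3D_FBSlow, and leaving out both libraries that stand apart, were added after the data were seen. No library was excluded from the reported values.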

Results

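RNA depleted of ribosomal RNA was sequenced in 18 libraries of the established human lines H460, from a large cell lung carcinoma, and MCF7, from an estrogen receptor positive breast carcinoma. Each line was grown as a monolayer (2D) and as spheroids in a low-serum medium (3D_FBSlow) and in a serum-free spheroid medium (3D_SM), with 3 libraries per group. In replicate order 1 to 3, the H460 libraries held 14287860, 11896677 and 24615277 estimated counts in 2D, 13592085, 21683141 and 27057239 in 3D_FBSlow, and 22620884, 28955463 and 27448544 in 3D_SM. The MCF7 libraries held 15467054, 17117251 and 18490559 in 2D, 12591338, 12412903 and 16949248 in 3D_FBSlow, and 19499405, 14938828 and 16953099 in 3D_SM. The 2D medium held 10% FBS and was RPMI for H460 and DMEM for MCF7, so each comparison of 3D with 2D changed the medium together with the growth form. The labels say "in triplicate" without saying whether the cultures were grown apart, so the p-values below may measure technical spread only.

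In each of 2 groups 1 library stood apart. It was compared with the other 2 of its group in the fit of its line, assuming that a lone library varies like the rest, a test chosen after these libraries were seen. Lists were tested with camera at a preset or an estimated correlation. In H460 3D_FBSlow replicate 3, 3659 of 14396 genes and 15 of 35 lists were called. Cholesterol (mean log2 fold change 0.75, adjusted p 1.7e-22 or 0.11), mitosis (0.60, 8.3e-20 or 0.036) and histone genes (0.69, 8.3e-16 or 0.083) came first and were higher. The NF-kB list was higher too (0.86, 3.1e-07 or 0.22), and EGF and FGF early response genes were not called (0.063). In MCF7 3D_SM replicate 2, 3075 of 14420 genes and 21 lists were called. NF-kB (1.78, 3.2e-24 or 0.0039) and EGF and FGF genes (0.88, 2.5e-09 or 0.12) were higher and mitosis genes lower (-0.57, 3.4e-11 or 0.14). In H460 3D_FBSlow, the NF-kB and inflammatory cytokine list averaged -0.82 and -0.84 log2 CPM relative to 2D in replicates 1 and 2, and -0.02 in replicate 3, where CXCL1 stood at 62.4 CPM against 10.7 and 10.7, and EGR1 at 44.2 against 4.67 and 4.80. In MCF7 3D_SM the NF-kB list averaged 2.41 above 2D in replicate 2, against 0.73 and 0.68 in replicates 1 and 3, and the EGF and FGF list 2.18 against 1.36 and 1.38. MUC2, a secreted mucin, stood at 565 CPM in that library against 72.9 and 96.1. CXCL1, EGR1 and MUC2 are quoted here because of these values. Between replicates 1 and 2 of H460 3D_FBSlow, 6.68% of 5058 genes differed at a chi-square p under 0.05, where sampling alone gives 5%, against 48.4% and 49.6% for the pairs with replicate 3. In MCF7 3D_SM the pairs with replicate 2 differed in 60.5% and 51.7% of genes and the remaining pair in 39.4%. Reads of 28S and 45S ribosomal RNA made 4.04, 3.96 and 0.772% of the H460 3D_FBSlow libraries and 3.69, 9.57 and 7.23% of the MCF7 3D_SM libraries, and MALAT1 1.95, 2.01 and 1.33% and 3.69, 6.72 and 5.61%. Some counts are also given without these libraries.

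ALDOC and ENO2 are named in the series title, so they were chosen by the study on these samples. ALDOC (chromosome 17, 28573115 to 28577264, minus strand, GRCh38) encodes aldolase C, an isozyme of the glycolytic enzyme that splits fructose bisphosphate. ENO2 (chromosome 12, 6913745 to 6923698, plus strand) encodes the neuronal form of enolase, a later step of glycolysis. Levels are given as mean CPM (counts relative to the TMM-scaled library total) ± SD and log2 fold changes ± SE, with n = 3 libraries per group throughout. In H460, ALDOC rose in 3D_FBSlow (2.70 ± 0.10, from 9.66 ± 1.23 to 62.2 ± 2.86 CPM, FDR 1.4e-08) and in 3D_SM (3.71 ± 0.11, from 9.66 ± 1.23 to 125 ± 6.62 CPM, FDR 5.3e-09). In MCF7 it rose in 3D_FBSlow (5.04 ± 0.17, from 9.47 ± 1.15 to 310.1 ± 52.6 CPM, FDR 3.8e-08) and in 3D_SM (4.68 ± 0.17, from 9.47 ± 1.15 to 242 ± 32.2 CPM, FDR 4.6e-08). ENO2 rose in H460 in 3D_FBSlow (1.66 ± 0.33, from 14.9 ± 2.52 to 47.0 ± 19.9 CPM, FDR 0.0036) and in 3D_SM (2.02 ± 0.33, from 14.9 ± 2.52 to 59.7 ± 7.62 CPM, FDR 0.0017), and in MCF7 in 3D_FBSlow (3.65 ± 0.25, from 18.5 ± 1.04 to 232 ± 33.5 CPM, FDR 5.4e-06) and in 3D_SM (3.92 ± 0.25, from 18.5 ± 1.04 to 279 ± 107 CPM, FDR 2.0e-06). ENO2 was uneven in H460 3D_FBSlow, at 57.8, 59.1 and 24.1 CPM in replicates 1 to 3. Between the spheroid media, ALDOC was higher in 3D_SM in H460 (1.01 ± 0.09, FDR 1.2e-05) and did not pass in MCF7 (-0.36 ± 0.14, FDR 0.067). That MCF7 call is made when all 18 libraries are fitted together (adjusted p 0.0224), without 3D_FBSlow replicate 1 (-0.49, 0.0205) or without 3D_SM replicate 1 (-0.47, 0.0184). ENO2 did not pass between the media in H460 (0.36 ± 0.31, FDR 0.36) or MCF7 (0.26 ± 0.22, FDR 0.35). The common isozymes, quoted for scale and chosen after their values were seen, were more abundant in each of the 6 groups: in 2D, ALDOA stood at 1013 ± 78.0 CPM in H460 and 369.5 ± 19.4 in MCF7, and ENO1 at 2183 ± 195 and 571 ± 13.1.

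**Figure D1:**
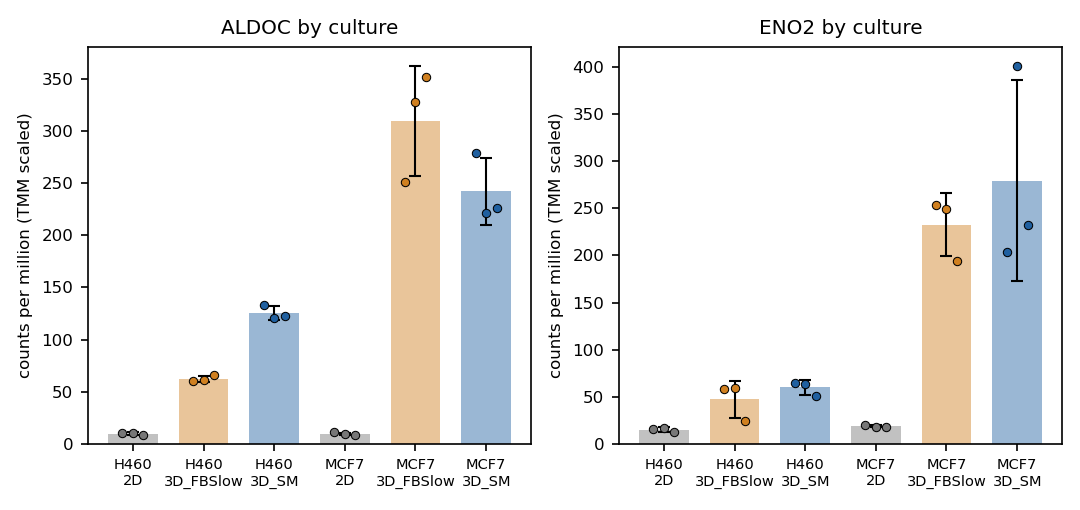
ALDOC and ENO2 in CPM in the 6 groups of libraries, with bars for the mean, error bars for the SD and points for the 3 libraries of each group. In both lines every 3D library lies above the mean of 2D, which is 9.66 and 9.47 CPM for ALDOC and 14.9 and 18.5 CPM for ENO2.

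3D_FBSlow against 2D in H460 asks what differs in spheroids under nutrient restriction. CA9, the hypoxia-induced carbonic anhydrase of the cell surface, had 0 counts in 2D and 1162 in 3D_FBSlow, at least 325-fold higher against a floor of 3 counts over the group. Other large rises were PPFIA4, a scaffold protein of the liprin family (7.51 ± 0.77, from 0.398 ± 0.0573 to 76.1 ± 43.2 CPM, FDR 1.7e-04), CP, the copper-carrying ferroxidase ceruloplasmin (6.43 ± 0.20, from 0.779 ± 0.363 to 65.2 ± 0.325 CPM, FDR 4.4e-09), CHI3L2, a chitinase-like secreted protein (5.92 ± 0.56, FDR 1.8e-05), CPLX2, which controls vesicle release (5.67 ± 1.20, FDR 0.0079, with 41.7, 45.1 and 188 CPM in replicates 1 to 3), and NRN1, neuritin (5.67 ± 0.54, FDR 2.8e-05). The largest falls were in MARCH4, a ubiquitin ligase (-7.11 ± 0.41, FDR 3.1e-07), UNC5B, a netrin receptor (-6.72 ± 0.25, from 120 ± 6.09 to 1.24 ± 0.558 CPM, FDR 1.6e-08), CHAC1, a glutathione-degrading enzyme induced by ATF4 (-5.73 ± 0.32, from 22.5 ± 0.622 to 0.374 ± 0.216 CPM, FDR 1.6e-07), ANKRD1, a target of YAP (-5.50 ± 0.23, FDR 1.7e-08), ADM2, a vasoactive peptide (-5.13 ± 0.21, FDR 1.5e-08), and IL1RL1, the receptor of interleukin 33 (-5.07 ± 0.29, FDR 1.3e-07). Without 3D_FBSlow replicate 3, CPLX2 rose by 4.601 and IL1RL1 fell by 6.035.

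ATF4 is the transcription factor of the amino acid and integrated stress response, and its targets formed the strongest block. The gene lists were fixed before the data were examined. Counts of members that rose or fell use the FDR over all genes tested, and the counts adjusted over the list alone are the same unless they are given. The median is that of the members' log2 fold changes. A list is called at a camera adjusted p under 0.05, and after "or" follows its value with an estimated correlation. Of 21 measured, 0 rose and 20 fell, median -2.06, adjusted p 1.7e-34 or 0.0034. WARS, a tRNA ligase (-2.64 ± 0.08, from 1045 ± 22.5 to 168 ± 6.93 CPM, FDR 4.4e-09), SESN2, which restrains mTORC1 (-2.86 ± 0.09, from 62.3 ± 3.28 to 8.5 ± 0.729 CPM, FDR 5.0e-09), and GDF15, a stress cytokine (-4.52 ± 0.16, from 62.6 ± 5.17 to 2.79 ± 0.506 CPM, FDR 9.9e-09), fell. Of 22 p53 targets, 1 rose and 18 fell, or 1 and 19 adjusted over the list alone, median -1.01, adjusted p 2.1e-15 or 0.012. SESN2 and GDF15 belong to both lists, the p53 list gave 2.1e-09 or 0.023 without them, and AEN, a p53-induced nuclease, fell as well (-1.74 ± 0.09). Of 14 genes of glutamine and amino acid use, 1 rose and 11 fell, median -0.82, adjusted p 9.3e-09 or 0.18, among them the transporter SLC7A5 (-1.96 ± 0.10, from 423 ± 22.8 to 109 ± 12.1 CPM) and the asparagine synthetase ASNS (-3.30 ± 0.17, from 339 ± 15.9 to 34.2 ± 7.26 CPM). Of 16 genes of the pentose phosphate and serine pathways, 4 rose and 8 fell, or 4 and 9 adjusted over the list alone, median -0.25, adjusted p 2.6e-04 or 0.32, and PSAT1, of serine synthesis, fell (-3.07 ± 0.17). That list call ended on TPM (adjusted p 0.0514 and 0.0543). Among 23 hypoxia genes outside glycolysis, 18 rose and 1 fell, median 1.05, adjusted p 2.3e-13 or 0.18. BNIP3L, a mitophagy receptor (2.20 ± 0.10, from 38.9 ± 2.44 to 179.6 ± 16.3 CPM), and EGLN3, an oxygen-sensing hydroxylase (2.85 ± 0.14, from 2.77 ± 0.418 to 19.9 ± 1.98 CPM), rose. The median is unchanged with CA9 at its bound. Among 25 glycolysis genes, 17 rose and 2 fell, median 0.72, adjusted p 2.5e-09 or 0.25. PFKFB4, which makes an activator of phosphofructokinase (3.48 ± 0.17, from 4.7 ± 0.513 to 51.8 ± 10.5 CPM), and PGK1 (1.60 ± 0.08, from 521 ± 33.9 to 1582 ± 73.4 CPM) rose. That count includes ALDOC and ENO2 and is not independent evidence on them.

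Cytoskeletal, YAP and SRF target genes also went down. Of 24, 1 rose and 19 fell, or 1 and 20 adjusted over the list alone, median -1.02, adjusted p 1.2e-11 or 0.066. AJUBA, a junction protein (-1.95 ± 0.08, from 88.0 ± 1.95 to 22.9 ± 1.34 CPM), and TEAD1, the DNA-binding partner of YAP (-1.43 ± 0.08), fell. Of 28 mitosis genes, 0 rose and 19 fell, or 0 and 23 adjusted over the list alone, median -0.78, adjusted p 3.7e-07 or 0.47. The kinases PLK1 (-1.12 ± 0.11, from 59.2 ± 3.51 to 27.2 ± 0.833 CPM) and AURKB (-1.18 ± 0.11) fell. Of 36 cytosolic ribosomal protein genes, 31 rose and 0 fell, or 32 and 0 adjusted over the list alone, median 0.43, adjusted p 1.2e-04 or 0.64. Of 23 cholesterol genes, 14 rose and 1 fell, median 0.75, adjusted p 0.0023 or 0.7. DHCR24, the last reduction step (1.79 ± 0.16), rose. For the insulin and FOXO list, 11 rose and 2 fell of 18, or 12 and 2 adjusted over the list alone, adjusted p 0.017 or 0.47. IGFBP3, which binds insulin-like growth factors (3.04 ± 0.19, from 454 ± 23.6 to 3718 ± 1054 CPM), rose. For EGF and FGF early response genes, 4 rose and 11 fell of 23, adjusted p 0.033 or 0.32. The phosphatase DUSP5 (-2.40 ± 0.19, from 87.3 ± 2.76 to 16.4 ± 4.16 CPM) fell. Both calls ended when all 18 libraries were fitted together (0.106 and 0.0727). For heat shock proteins, 8 rose and 3 fell of 15, or 8 and 4 adjusted over the list alone, adjusted p 0.038 or 0.47, a call that ended without 2D replicate 2 (0.05) or 3 (0.0513) or 3D_FBSlow replicate 3 (0.109). For fatty acid oxidation, 8 rose and 2 fell of 15, adjusted p 0.013 or 0.47, and for epithelial junctions and keratins, 3 rose and 7 fell of 16, adjusted p 0.015 or 0.23. On TPM those were 0.0807 to 0.144 and 0.125 to 0.138. Of the 15 lists called, the ATF4 and p53 lists are the 2 called with an estimated correlation. Lists not called include ER stress, in which 3 rose and 8 fell of 20, so that the chaperone HYOU1 fell (-1.38 ± 0.08) while HSP90B1 rose (1.01 ± 0.08). They also include the TCA cycle (0 rose and 8 fell of 23), autophagy and lysosome (6 rose and 6 fell of 21), estrogen receptor targets (5 rose and 6 fell of 14) and metallothioneins (3 rose and 2 fell of 7, or 4 and 2 adjusted over the list alone).

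Of 14396 genes tested in H460 with edgeR at an FDR under 0.05, 7268 differed between 3D_FBSlow and 2D, 3662 higher and 3606 lower, and 2064 of them at least 2-fold. The count was 8701 without 3D_FBSlow replicate 3. It was 6361 with replicates 1 and 2 of 3D_FBSlow summed as 1 library, a setting chosen after the data were seen.

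3D_SM against 2D in H460 sets growth-factor-supplied spheroids without serum against the monolayer. CA9 went from 0 to 1157 counts, at least 247-fold higher. PPFIA4 (6.43 ± 0.78, from 0.398 ± 0.0573 to 35.8 ± 0.677 CPM, FDR 5.5e-04), STC1, a secreted glycoprotein induced by hypoxia (5.99 ± 0.45, from 4.09 ± 0.124 to 259 ± 24.1 CPM, FDR 2.8e-05), NRN1 (4.80 ± 0.55, FDR 1.3e-04), CPLX2 (4.46 ± 1.20, FDR 0.024) and ITGA2B, an integrin of platelets (4.44 ± 0.37, from 0.983 ± 0.0612 to 21.6 ± 0.44 CPM, FDR 1.4e-05), were the other large rises. The CPLX2 call ended in 7 settings, among them without 2D replicate 1 (0.059), 2 (0.076) or 3 (0.078) or 3D_SM replicate 2 (0.062), with adjusted p from 8.3e-06 to 0.078 over its alternatives. The largest falls were in ABCG1, a cholesterol exporter (-5.01 ± 0.33, from 29.1 ± 1.31 to 0.892 ± 0.263 CPM, FDR 1.6e-06), UNC5B (-4.78 ± 0.20, FDR 8.3e-08), HES1, a target of Notch (-4.76 ± 0.27, from 94.5 ± 2.64 to 3.5 ± 0.811 CPM, FDR 1.2e-06), AKNA (-4.70 ± 0.21, FDR 8.3e-08), IGFN1 (-4.46 ± 0.67, FDR 0.0012) and C10orf54, which encodes the immune checkpoint VISTA (-4.41 ± 0.15, FDR 1.6e-08).

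Lipid synthesis genes rose together in 3D_SM. Of 23 cholesterol genes, 21 rose and 0 fell, or 22 and 0 adjusted over the list alone, median 2.52, adjusted p 3.1e-38 or 0.089. DHCR24 (3.21 ± 0.16, from 21.2 ± 0.532 to 197 ± 12.4 CPM, FDR 1.9e-07) and MVD, of the mevalonate pathway (2.81 ± 0.17), rose. Of 15 fatty acid synthesis genes, 12 rose and 1 fell, or 13 and 1 adjusted over the list alone, median 1.21, adjusted p 1.7e-12 or 0.076. The desaturase SCD (2.09 ± 0.14, from 724 ± 10.2 to 3081 ± 174 CPM, FDR 8.6e-07) and ACSS2, which makes acetyl-CoA from acetate (2.24 ± 0.10), rose. ATF4 targets were again low: 1 rose and 20 fell of 21, median -1.93, adjusted p 3.1e-38 or 0.002. WARS (-2.65 ± 0.08, from 1045 ± 22.5 to 166 ± 10.98 CPM, FDR 6.3e-09) and GDF15 (-3.52 ± 0.14, from 62.6 ± 5.17 to 5.46 ± 0.968 CPM) fell. Of p53 targets, 0 rose and 13 fell of 22, or 1 and 15 adjusted over the list alone, median -0.49, adjusted p 1.5e-09 or 0.012, and 9.1e-05 or 0.064 without SESN2 and GDF15. BBC3, which encodes PUMA (-2.58 ± 0.18), fell. For glutamine and amino acid use, 0 rose and 10 fell of 14, median -0.66, adjusted p 1.2e-07 or 0.11. For the pentose phosphate and serine pathways, 2 rose and 9 fell of 16, median -0.41, adjusted p 2.4e-04 or 0.21. For hypoxia genes, 16 rose and 2 fell of 23, or 18 and 2 adjusted over the list alone, median 1.37, adjusted p 8.3e-17 or 0.089. EGLN3 rose (3.34 ± 0.13, from 2.77 ± 0.418 to 28 ± 1.78 CPM), and the median is the same with CA9 at its bound. For glycolysis, 18 rose and 1 fell of 25, or 19 and 1 adjusted over the list alone, median 0.85, adjusted p 8.3e-15 or 0.091. PFKFB4 (3.44 ± 0.17, from 4.7 ± 0.513 to 50.1 ± 3.79 CPM) and PGK1 (1.70 ± 0.08) rose.

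DNA replication genes rose in 3D_SM: 18 rose and 0 fell of 29, or 20 and 1 adjusted over the list alone, median 0.49, adjusted p 1.5e-05 or 0.47. The helicase subunit MCM4 (0.93 ± 0.10, from 78.8 ± 2.2 to 150.3 ± 3.08 CPM) and GINS2 (1.14 ± 0.13) rose. Heat shock proteins rose: 13 rose and 0 fell of 15, or 14 and 0 adjusted over the list alone, median 0.72, adjusted p 6.1e-08 or 0.085. In the respiratory chain, 16 rose and 3 fell of 43, adjusted p 0.0051 or 0.76. In fatty acid oxidation, 8 rose and 2 fell of 15, or 9 and 2 adjusted over the list alone, adjusted p 5.8e-04 or 0.21. YAP and SRF targets fell: 2 rose and 17 fell of 24, median -0.66, adjusted p 2.6e-08 or 0.085. EGF and FGF early response genes were lower in this medium, which contains EGF and bFGF: 3 rose and 10 fell of 23, adjusted p 0.019 or 0.18. DUSP5 (-2.19 ± 0.19, from 87.3 ± 2.76 to 19.1 ± 4.33 CPM) fell. Retinoic acid targets were lower, 0 rose and 3 fell of 9, or 0 and 2 adjusted over the list alone, adjusted p 0.011 or 0.18. The retinal reductase DHRS3 fell (-4.05 ± 0.18, from 26.4 ± 1.45 to 1.59 ± 0.23 CPM, FDR 4.1e-08), and the list call ended with all 18 libraries fitted (0.097) and on TPM (up to 0.154). In the stem cell list, 3 rose and 10 fell of 19, adjusted p 0.044 or 0.35. That call ended in 4 settings at 0.0553 to 0.0898, the bounds being those without 3D_SM replicate 1 and 2. In the fibroblast list, whose genes H460 itself expresses, 4 rose and 0 fell of 5, adjusted p 0.011 or 0.11. LUM rose (2.75 ± 0.20, from 4.42 ± 0.66 to 29.2 ± 2.78 CPM), and the list call ended on TPM (0.0503 to 0.176) and with a stricter filter (0.0537). In the TCA cycle list, 8 rose and 0 fell of 23, adjusted p 0.031 or 0.71, a call that ended without 3D_SM replicate 1 (0.0583). Of the 18 lists called, the ATF4 and p53 lists are again the 2 called with an estimated correlation. Mitosis (5 rose and 2 fell of 28, or 4 and 2 adjusted over the list alone), ribosomal proteins (0 rose and 13 fell of 36) and ER stress (9 rose and 6 fell of 20) were not called. In all 6036 of 14396 genes differed, 2959 higher and 3077 lower, 1494 of them at least 2-fold.

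3D_SM against 3D_FBSlow in H460 compares the spheroid media. The largest rises in 3D_SM were LINC00707, a long non-coding RNA (3.86 ± 0.24, from 0.355 ± 0.109 to 5.5 ± 0.837 CPM, FDR 1.0e-06), HYAL1, a hyaluronidase (3.47 ± 0.28, from 2.71 ± 1.24 to 31.7 ± 8.16 CPM, FDR 1.1e-05), TMEM154 (3.41 ± 0.20, FDR 6.8e-07), DCLK1, a microtubule-linked kinase (2.95 ± 0.38, FDR 4.6e-04), MARCH4 (2.92 ± 0.55, FDR 0.0015, ended on TPM at 0.076, over 1.6e-07 to 0.12 in all) and CDCP1, a membrane glycoprotein (2.92 ± 0.35, FDR 3.2e-04). DCLK1 rose by 3.74 without 3D_FBSlow replicate 3, and MARCH4 by 2.32 without 3D_SM replicate 3. The largest falls were in DHRS3 (-4.36 ± 0.17, from 32.9 ± 6.35 to 1.59 ± 0.23 CPM, FDR 7.8e-08), CP (-3.75 ± 0.15, from 65.2 ± 0.325 to 4.81 ± 0.707 CPM, FDR 7.8e-08), RARB, a retinoic acid receptor (-2.91 ± 0.12, from 34.2 ± 3.32 to 4.54 ± 0.523 CPM, FDR 7.8e-08), FOSB (-2.84 ± 0.38, FDR 2.5e-04), ZMAT1 (-2.74 ± 0.31, FDR 7.0e-05) and C1R-2 (-2.66 ± 0.14, FDR 4.9e-07). With them the retinoic acid list fell: 1 rose and 5 fell of 9, median -1.15, adjusted p 1.3e-06 or 0.19. Of 28 mitosis genes, 28 rose and 0 fell, median 0.89, adjusted p 1.0e-12 or 0.49. BUB1 (1.27 ± 0.14, from 53.3 ± 13.98 to 129 ± 3.5 CPM) and CDC20 (1.21 ± 0.14) rose. Of DNA replication genes, 23 rose and 1 fell of 29, or 24 and 1 adjusted over the list alone, median 0.59, adjusted p 4.1e-08 or 0.52. RRM2, of nucleotide reduction (1.46 ± 0.10, from 146 ± 20.6 to 403 ± 24.5 CPM), rose. Of cholesterol genes, 23 rose and 0 fell of 23, median 1.60, adjusted p 1.1e-22 or 0.36. Of fatty acid synthesis genes, 11 rose and 0 fell of 15, median 0.57, adjusted p 9.6e-08 or 0.19. SCD (1.76 ± 0.14, from 908 ± 221 to 3081 ± 174 CPM) rose. Ribosomal protein genes were lower: 0 rose and 33 fell of 36, or 0 and 35 adjusted over the list alone, median -0.62, adjusted p 2.2e-11 or 0.52. RPL37 (-0.90 ± 0.08, from 1259 ± 27.9 to 676 ± 63.2 CPM) fell.

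Genes of mitochondrial energy metabolism were higher in 3D_SM. Of TCA cycle genes 15 rose and 0 fell of 23, or 16 and 0 adjusted over the list alone, adjusted p 5.0e-05 or 0.52. Of respiratory chain genes 18 rose and 0 fell of 43, or 17 and 0 adjusted over the list alone, adjusted p 8.4e-04 or 0.89. Glycolysis (4 rose and 3 fell of 25, or 4 and 2 adjusted over the list alone, adjusted p 0.53) and hypoxia genes (6 rose and 7 fell of 23, adjusted p 0.95) were not called. For p53 targets, 10 rose and 1 fell of 22, adjusted p 0.0015 or 0.19. For ER stress, 12 rose and 2 fell of 20, adjusted p 0.0091 or 0.49. For heat shock proteins, 8 rose and 1 fell of 15, adjusted p 0.0078 or 0.49. The insulin and FOXO list fell, 2 rose and 11 fell of 18, adjusted p 0.0028 or 0.51. IGFBP3 (-2.06 ± 0.18, from 3718 ± 1054 to 893 ± 72.6 CPM) fell. The cytoskeletal list (9 rose and 0 fell of 24, adjusted p 0.027 or 0.52) ended in 5 settings at 0.0504 to 0.0927, among them without 3D_FBSlow replicate 3 (0.069) or 3D_SM replicate 3 (0.0713). The histone list (6 rose and 0 fell of 15, adjusted p 0.0482 or 0.92) ended in 10 settings at 0.0513 to 0.196, and reads of histone genes are shared among near-identical copies. None of the 14 lists called was called with an estimated correlation, where the smallest adjusted p was 0.19. Extracellular matrix genes went both ways (6 rose and 13 fell of 25, or 7 and 14 adjusted over the list alone), with the integrin ITGA6 up (1.70 ± 0.07). In all 7180 genes differed, 3539 higher and 3641 lower, 1652 at least 2-fold, and 9118 differed without 3D_FBSlow replicate 3. On log2(TPM + 1) the split was 3528 higher and 2101 lower.

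3D_FBSlow against 2D in MCF7 asks the same question of the breast line. ANKRD37, a hypoxia-induced ankyrin repeat gene, rose most (7.28 ± 0.38, from 0.701 ± 0.217 to 110.4 ± 13.6 CPM, FDR 1.2e-06), followed by MMP1, a collagenase (5.33 ± 1.45, from 0.268 ± 0.0992 to 11.2 ± 1.66 CPM, FDR 0.018), LOX, which cross-links collagen (5.13 ± 1.18, from 0.403 ± 0.176 to 14.3 ± 2.57 CPM, FDR 0.0083), ALDOC, HIF1A-AS2, an antisense RNA at the HIF1A locus (5.01 ± 0.51, FDR 7.4e-05), and ANGPTL4, a lipase inhibitor (4.93 ± 0.30, from 5.35 ± 1.08 to 162 ± 4.1 CPM, FDR 3.2e-06). The largest falls were in LRRC37A4P, a pseudogene (-5.41 ± 0.23, FDR 2.2e-07), CLDN1 (-4.20 ± 0.33, from 25.2 ± 1.48 to 1.39 ± 0.377 CPM, FDR 1.1e-05), TGFB2 (-4.10 ± 0.26, from 30.0 ± 0.727 to 1.73 ± 0.435 CPM, FDR 2.6e-06), CAV1, caveolin (-3.90 ± 0.71, from 14.3 ± 1.1 to 0.96 ± 0.137 CPM, FDR 0.0024), CLIP4 (-3.66 ± 1.08, FDR 0.024) and PVRIG2P, another pseudogene (-3.57 ± 0.72, FDR 0.0045). The MMP1 call ended in 6 settings, among them without 2D replicate 1 (0.066), 2 (0.058) or 3 (0.064), over 0.0085 to 0.081 in all. The CLIP4 call ended in 6, among them without 2D replicate 2 (0.052) or 3 (0.053) or 3D_FBSlow replicate 2 (0.055) or 3 (0.074), over 0.006 to 0.078 in all. The LOX call ended on log2(TPM + 1), at 0.054, over 5.5e-04 to 0.058 in all.

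Hypoxia and glycolysis genes formed the strongest block. Of 24 hypoxia genes, 22 rose and 0 fell, median 3.18, adjusted p 1.0e-51 or 0.0078. PDK1, which shuts pyruvate out of the TCA cycle (3.24 ± 0.10, from 16.4 ± 1.16 to 156 ± 7.53 CPM, FDR 2.8e-08), and the collagen hydroxylase P4HA2 (3.38 ± 0.11, from 20.3 ± 0.167 to 212 ± 19.6 CPM) rose. Of 23 glycolysis genes, 21 rose and 0 fell, median 2.01, adjusted p 2.6e-47 or 0.0078. LDHA, which makes lactate (3.01 ± 0.11, from 336 ± 4.43 to 2712 ± 66.6 CPM, FDR 3.9e-08), and PFKFB4 (3.78 ± 0.13, from 10.0 ± 1.66 to 137 ± 9.42 CPM) rose. These are the 2 of 16 called lists that were called with an estimated correlation. ATF4 targets rose: 16 rose and 1 fell of 21, or 16 and 2 adjusted over the list alone, median 0.70, adjusted p 2.7e-07 or 0.0547. VLDLR (2.50 ± 0.12, from 5.59 ± 0.176 to 31.6 ± 3.4 CPM), GPT2, of alanine metabolism (1.26 ± 0.09, from 38.1 ± 1.09 to 91.3 ± 3.83 CPM), and WARS (1.01 ± 0.10, from 80.2 ± 1.3 to 161 ± 7.14 CPM) rose. ER stress genes rose: 17 rose and 0 fell of 20, median 1.00, adjusted p 1.2e-12 or 0.0547. Cholesterol genes rose: 19 rose and 1 fell of 23, median 1.17, adjusted p 6.9e-18 or 0.11. Fatty acid synthesis genes rose: 9 rose and 0 fell of 15, median 0.85, adjusted p 1.4e-10 or 0.0547. SCD (3.27 ± 0.12, from 641 ± 37.9 to 6167 ± 267 CPM) rose. EGF and FGF early response genes rose: 15 rose and 2 fell of 25, or 16 and 2 adjusted over the list alone, median 1.28, adjusted p 3.5e-07 or 0.34. JUN (1.30 ± 0.10) and DUSP6 (1.53 ± 0.15, from 4.69 ± 0.484 to 13.6 ± 1.96 CPM) rose.

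Cell cycle and translation genes moved in part. DNA replication genes rose: 21 rose and 0 fell of 29, median 0.53, adjusted p 1.1e-06 or 0.37. RRM2 (1.83 ± 0.16, from 71.6 ± 0.832 to 254 ± 2.38 CPM) rose. Mitosis genes were not called (1 rose and 2 fell of 28, or 0 and 0 adjusted over the list alone, adjusted p 0.75). Ribosomal protein genes rose: 25 rose and 0 fell of 36, or 28 and 0 adjusted over the list alone, adjusted p 4.4e-04 or 0.65. Respiratory chain genes rose (18 rose and 0 fell of 43, or 25 and 0 adjusted over the list alone, adjusted p 7.4e-04 or 0.65), as did the TCA cycle (11 rose and 0 fell of 23, or 12 and 0 adjusted over the list alone, adjusted p 0.015 or 0.61), heat shock proteins (11 rose and 0 fell of 14, adjusted p 4.3e-04 or 0.36, with HSP90AB1 at 0.99 ± 0.09), glutamine and amino acid use (9 rose and 1 fell of 15, or 10 and 1 adjusted over the list alone, adjusted p 0.01 or 0.36, and 0.149 without 3 members on the ATF4 list), histones (9 rose and 0 fell of 17, or 14 and 0 adjusted over the list alone, adjusted p 0.0025 or 0.57) and glucocorticoid receptor targets (6 rose and 2 fell of 13, or 7 and 2 adjusted over the list alone, adjusted p 7.4e-04 or 0.0547, with the clock gene PER1 at 2.57 ± 0.21). The p53 targets fell (2 rose and 10 fell of 22, adjusted p 0.033 or 0.34, 0.051 without 3D_FBSlow replicate 1), yet GDF15, on that list and the ATF4 list, rose (2.62 ± 0.27, from 14.3 ± 0.73 to 88.0 ± 6.8 CPM, FDR 7.1e-05). Estrogen receptor targets were not called (9 rose and 2 fell of 19, or 9 and 3 adjusted over the list alone, adjusted p 0.1), with TFF3 up (2.53 ± 0.25), nor were stem cell genes (2 rose and 8 fell of 18, adjusted p 0.072), with HES1 down (-2.70 ± 0.09). The 3 measured leukocyte markers were mixed (2 rose and 1 fell of 3, adjusted p 0.56), with CD68, a lysosomal protein that is not restricted to leukocytes, up (4.21 ± 0.95, from 0.674 ± 0.278 to 12.8 ± 3.2 CPM, FDR 0.0079). In all 6435 of 14420 genes differed, 3154 higher and 3281 lower, 1837 at least 2-fold. Scaled by library totals only, the median of all genes moved by -0.22 and the split became 1803 higher and 4812 lower, and on log2(TPM + 1) it was 1652 and 2913.

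3D_SM against 2D in MCF7 gave rises that were often highest in replicate 2. LRRC15, a membrane protein, rose (8.44 ± 1.61, from 0.129 ± 0.042 to 47.1 ± 64.2 CPM, FDR 0.0037) with 9.70, 121 and 10.4 CPM in replicates 1 to 3, MUC2 (8.07 ± 1.13, FDR 8.1e-04) with 72.9, 565 and 96.1, CASP14, a caspase of keratinised cells (7.25 ± 1.17, FDR 0.0013), with 10.1, 86.6 and 14.9, and KRT16, a stress keratin (6.88 ± 0.98, FDR 4.8e-04), with 5.03, 25.8 and 4.25. S100A9, an inflammatory calcium-binding protein (7.25 ± 1.97, FDR 0.018), rose by 3.76 without replicate 2, and its call ended without 2D replicate 1 (0.068), 2 (0.072) or 3 (0.077), over 0.0024 to 0.11 in all. GJA1, the gap junction protein connexin 43, rose in each of the 3 libraries (7.36 ± 0.34, from 0.974 ± 0.267 to 162 ± 57.7 CPM, FDR 2.2e-07). LRRC15 was not called on log2(TPM + 1), at 0.066, over 3.2e-06 to 0.066 in all. The largest falls were in ATRNL1 (-6.99 ± 0.28, FDR 7.0e-08), TGFB2 (-6.69 ± 0.33, FDR 2.1e-07), SULF1, which trims heparan sulfate (-6.51 ± 0.13, from 568 ± 24.4 to 6.23 ± 0.227 CPM, FDR 9.6e-10), UGT2B15, which conjugates androgens (-5.58 ± 0.26, FDR 1.4e-07), LRRC37A4P (-5.18 ± 0.22, FDR 9.2e-08) and TARP (-4.86 ± 0.39, FDR 1.1e-05), whose reads overlap a T cell receptor locus. Without 3D_SM replicate 2, LRRC15 rose by 6.23, MUC2 by 6.54, CASP14 by 5.69 and KRT16 by 5.57, and TARP fell by 5.81. ATRNL1 fell by 7.74 without 3D_SM replicate 3. S100A9 and KRT16 folds rest on few reads in 2D (0.068 and 0.090 CPM).

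EGF and FGF early response genes rose strongly in MCF7 3D_SM: of 25, 20 rose and 1 fell, or 20 and 2 adjusted over the list alone, median 1.71, adjusted p 2.1e-16 or 0.16. The feedback genes DUSP6 (4.50 ± 0.15, from 4.69 ± 0.484 to 106 ± 13.4 CPM, FDR 2.2e-08) and SPRY4 (5.07 ± 0.32, from 0.978 ± 0.246 to 33.1 ± 9.46 CPM, FDR 1.4e-06) rose. Of hypoxia genes, 22 rose and 1 fell of 24, median 2.53, adjusted p 2.5e-31 or 0.032. EGLN3 rose (3.69 ± 0.14, from 6.46 ± 0.412 to 83.6 ± 9.11 CPM). Of glycolysis genes, 20 rose and 1 fell of 23, median 1.84, adjusted p 1.0e-27 or 0.032. These last 2 lists, of 17 called, were called with an estimated correlation. Estrogen receptor targets fell: 6 rose and 9 fell of 19, adjusted p 0.004 or 0.16. GREB1 (-4.34 ± 0.14, from 365 ± 20.7 to 18.1 ± 2.76 CPM, FDR 2.1e-08) and PGR, the progesterone receptor (-2.62 ± 0.11, from 32.5 ± 0.468 to 5.26 ± 0.438 CPM, FDR 7.1e-08), fell. That list was not called on TPM (0.193 to 0.297). Luminal markers, which include GREB1 and PGR, fell (3 rose and 4 fell of 10, adjusted p 0.012 or 0.16). That call ended on TPM (0.566 to 0.6) and without 3D_SM replicate 3 (0.0618). Cholesterol genes rose: 20 rose and 2 fell of 23, or 21 and 2 adjusted over the list alone, median 1.05, adjusted p 6.4e-15 or 0.16. INSIG1 (3.02 ± 0.12, from 60.3 ± 4.29 to 490.1 ± 74.1 CPM) rose. Fatty acid synthesis genes rose: 11 rose and 1 fell of 15, or 11 and 2 adjusted over the list alone, median 1.16, adjusted p 2.6e-11 or 0.089. SCD (3.58 ± 0.12, from 641 ± 37.9 to 7657 ± 720.4 CPM) rose. Ribosomal protein genes fell: 0 rose and 27 fell of 36, or 0 and 28 adjusted over the list alone, median -0.57, adjusted p 1.4e-05 or 0.65. The RNA composition shifted as well, with MALAT1 at 2.08 to 2.24% of a library in 2D, 2.52 to 4.90% in 3D_FBSlow and 3.69 to 6.72% in 3D_SM. ER stress genes rose (17 rose and 0 fell of 20, adjusted p 5.9e-07 or 0.16, with CALR at 1.48 ± 0.15), as did ATF4 targets (11 rose and 2 fell of 21, or 11 and 3 adjusted over the list alone, adjusted p 0.0083 or 0.26, with VLDLR at 2.21 ± 0.12).

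Matrix and integrin genes rose in MCF7 3D_SM (15 rose and 4 fell of 24, or 17 and 4 adjusted over the list alone, adjusted p 0.0019 or 0.32, with ITGB6 at 5.57 ± 0.24, from 1.05 ± 0.248 to 50.2 ± 10.6 CPM), as did epithelial genes (13 rose and 2 fell of 23, or 15 and 3 adjusted over the list alone, adjusted p 0.0031 or 0.33), DNA replication (13 rose and 1 fell of 29, adjusted p 0.0046 or 0.65) and autophagy and lysosome genes (11 rose and 0 fell of 22, adjusted p 0.01 or 0.26). Interferon-stimulated genes rose (8 rose and 1 fell of 16, or 10 and 1 adjusted over the list alone, adjusted p 0.026 or 0.65, with ISG15 at 2.00 ± 0.16, from 7.79 ± 1.08 to 31.2 ± 4.64 CPM), and that call ended without 3D_SM replicate 2 (0.0975). The NRF2 list (8 rose and 1 fell of 18, adjusted p 0.044 or 0.55, with the efflux pump ABCC3 at 2.99 ± 0.17, from 23.3 ± 0.627 to 185 ± 25.2 CPM) ended in 8 settings at 0.0522 to 0.141, the last without 3D_SM replicate 2, and heat shock proteins (7 rose and 2 fell of 14, adjusted p 0.027 or 0.63) ended in 5 settings at 0.0554 to 0.134, among them without 3D_SM replicate 1 (0.0923). NF-kB genes were not called (6 rose and 1 fell of 9, adjusted p 0.084), and RELB rose by 2.76 ± 0.52 with all libraries and by 1.83 without 3D_SM replicate 2. The p53 targets were not called and had a median of -0.13 against a mean of 0.26 (6 rose and 4 fell of 22, adjusted p 0.33), with the cell cycle inhibitor CDKN1A up (1.85 ± 0.08, from 59.7 ± 0.397 to 216 ± 7.07 CPM, FDR 7.1e-08). In all 6144 of 14420 genes differed, 3067 higher and 3077 lower, 2023 at least 2-fold, and 6793 without 3D_SM replicate 2. Scaled by library totals only, the median moved by -0.18 and the split was 2110 and 4533.

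3D_SM against 3D_FBSlow in MCF7 gave its largest rises in S100A9 (5.85 ± 1.80, FDR 0.03, 2.37 without 3D_SM replicate 2), MUC2 (5.64 ± 0.96, FDR 0.0026, 4.13 without 3D_SM replicate 2), CLCA2, an epithelial channel regulator (5.55 ± 0.28, from 0.487 ± 0.207 to 23.6 ± 3.74 CPM, FDR 8.5e-07), SBSN (5.30 ± 1.33, FDR 0.013, 2.80 without 3D_SM replicate 2), C1orf95 (5.16 ± 0.35, FDR 6.2e-06) and KRT16 (5.00 ± 0.85, FDR 0.0016, 3.70 without 3D_SM replicate 2). The S100A9 call ended without 3D_FBSlow replicate 1 (0.059), 2 (0.065) or 3 (0.081), over 0.0068 to 0.14 in all. The largest falls were in ATRNL1 (-5.87 ± 0.29, FDR 8.0e-07), SULF1 (-5.15 ± 0.12, from 222 ± 27.6 to 6.23 ± 0.227 CPM, FDR 6.5e-09), UGT2B15 (-5.12 ± 0.26, FDR 8.5e-07), GFRA1, a receptor of glial growth factors under estrogen control (-4.12 ± 0.11, from 368 ± 33.4 to 21.1 ± 2.1 CPM, FDR 1.4e-08), TARP (-4.01 ± 0.39, FDR 6.1e-05) and GREB1 (-3.55 ± 0.13, from 211 ± 19.7 to 18.1 ± 2.76 CPM, FDR 1.5e-07). TARP fell by 4.96 without 3D_SM replicate 2 and ATRNL1 by 6.64 without replicate 3, while MUC2 rose by 6.32 without 3D_FBSlow replicate 1 and S100A9 by 6.71 without replicate 2. Estrogen receptor targets fell as a list: 3 rose and 10 fell of 19, median -0.86, adjusted p 2.8e-07 or 0.13. Luminal markers fell (2 rose and 4 fell of 10, adjusted p 0.0043 or 0.17, 0.203 to 0.243 on TPM). All 36 ribosomal protein genes fell, median -1.02, adjusted p 1.3e-18 or 0.37. Respiratory chain genes fell: 1 rose and 23 fell of 43, or 1 and 24 adjusted over the list alone, median -0.44, adjusted p 2.7e-04 or 0.71. CYCS (-0.68 ± 0.10, from 93.5 ± 6.57 to 58.5 ± 5.38 CPM) fell. The p53 targets rose: 11 rose and 0 fell of 22, or 14 and 0 adjusted over the list alone, median 0.43, adjusted p 3.2e-04 or 0.17. CDKN1A (1.69 ± 0.08, from 67.1 ± 0.945 to 216 ± 7.07 CPM, FDR 4.2e-07) and BBC3 (1.26 ± 0.12) rose.

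Glycolysis (0 rose and 10 fell of 23, or 1 and 10 adjusted over the list alone, adjusted p 0.007 or 0.53, with LDHA at -0.74 ± 0.10, from 2712 ± 66.6 to 1624 ± 189.8 CPM) and hypoxia genes (2 rose and 10 fell of 24, adjusted p 0.011 or 0.53, with EGLN1 at -1.27 ± 0.12) were lower in MCF7 3D_SM than in 3D_FBSlow. So were glutamine and amino acid use (1 rose and 12 fell of 15, adjusted p 0.0015 or 0.34, with ASNS at -1.20 ± 0.12, from 138 ± 2.6 to 60.1 ± 11.4 CPM) and the pentose phosphate and serine pathways (1 rose and 9 fell of 16, adjusted p 0.0037 or 0.34). The TCA list (2 rose and 11 fell of 23, or 2 and 12 adjusted over the list alone, adjusted p 0.02 or 0.71) fell and ended without 3D_FBSlow replicate 3 (0.056) or 3D_SM replicate 2 (0.125), and the histone list (0 rose and 8 fell of 17, or 1 and 11 adjusted over the list alone, adjusted p 0.011 or 0.71) fell and ended without 3D_SM replicate 2 (0.102). Matrix and integrin genes rose (12 rose and 2 fell of 24, or 13 and 2 adjusted over the list alone, adjusted p 5.7e-05 or 0.34, with ITGA3 at 1.74 ± 0.10), as did the stem cell list (8 rose and 0 fell of 18, adjusted p 0.0055 or 0.22, with HES1 at 1.47 ± 0.08). EGF and FGF early response genes rose (14 rose and 3 fell of 25, or 14 and 6 adjusted over the list alone, adjusted p 5.7e-05 or 0.51, with DUSP6 at 2.98 ± 0.14, from 13.6 ± 1.96 to 106 ± 13.4 CPM), a list call that ended without 3D_SM replicate 2 (0.146). ATF4 targets were not called (4 rose and 8 fell of 21, or 4 and 9 adjusted over the list alone, adjusted p 0.054), nor were cholesterol (4 rose and 3 fell of 23, adjusted p 0.91), fatty acid synthesis (6 rose and 4 fell of 15, adjusted p 0.38), mesenchymal (2 rose and 3 fell of 10, adjusted p 0.84) or lung line marker genes (1 rose and 3 fell of 6, adjusted p 0.29). None of the 14 lists called was called with an estimated correlation, where the smallest adjusted p was 0.13. In all 6144 genes differed, 3136 higher and 3008 lower, 1745 at least 2-fold, and 6798 without 3D_SM replicate 2.

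Markers of other cell types with fewer than 3 measured members were tested as single genes. In H460, KDR, an endothelial receptor, rose in 3D_SM (3.23 ± 0.27, from 2.26 ± 0.245 to 21.6 ± 3.03 CPM) and in 3D_FBSlow (0.99 ± 0.29, ended on log2(TPM + 1) at 0.0981, 0.152 without a filter). CD68 rose in both (1.14 ± 0.11 and 0.78 ± 0.11), calls that ended with all 18 libraries fitted (0.101 and 0.245). CD14 rose in 3D_FBSlow (2.04 ± 0.30) and fell in 3D_SM (-0.94 ± 0.34, FDR 0.046, ended in 10 settings). In MCF7, COL1A1 rose in 3D_SM (1.02 ± 0.21, from 5.48 ± 0.551 to 11.2 ± 2.53 CPM, ended on TPM at up to 0.06), EMCN fell in 3D_FBSlow (-0.52 ± 0.19, FDR 0.046, ended in 13 settings) and ESAM was not called.

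**Figure D2:**
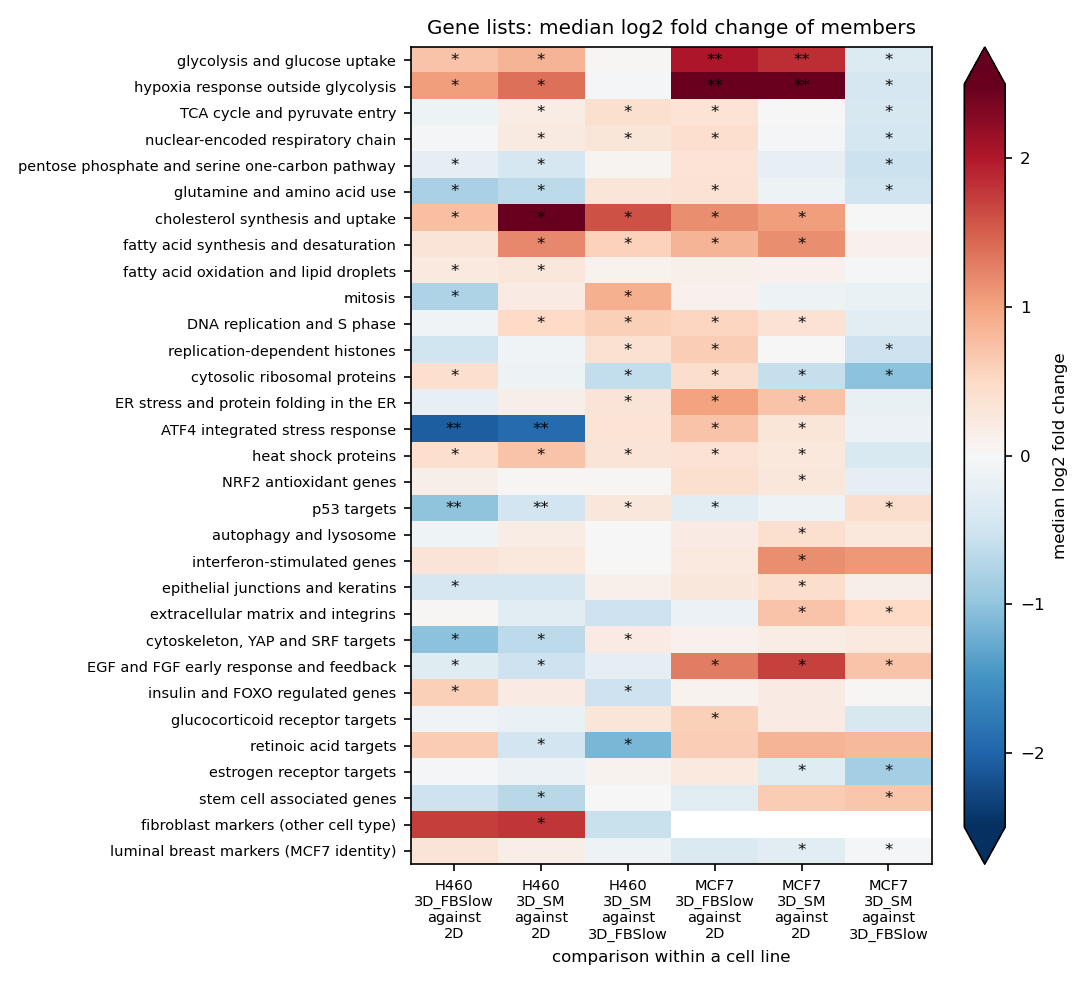
Median log2 fold change of the members of each gene list (colour, from -2.5 to 2.5) in the 6 comparisons within a line, for lists called in at least 1 of them, where a star marks a camera adjusted p under 0.05, a double star a call that also holds with an estimated correlation, and white a list with fewer than 3 measured members in that line. Glycolysis and hypoxia carry the double star in MCF7, and the ATF4 and p53 lists carry it in H460, in both comparisons with 2D.

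Genes that went the same way in both media and both lines are common to the 4 comparisons of 3D with 2D, in each of which serum was lowered or left out as well. Of 12871 genes tested in both lines, 334 were higher in all 4 comparisons with 2D, where 155 would be if the lines were independent (1332 in both media in H460 and 1497 in MCF7, two-sided Fisher's exact p 4.6e-48, across genes, which are not independent replicates). Lower in all 4 were 172, where 152 would be (1541 and 1266, p 0.0681). At least 2-fold in all 4 were 74 and 13. Besides CA9, the rises were led by STC1 (log2 fold changes 4.87, 5.99, 3.49 and 3.99 in H460 3D_FBSlow, H460 3D_SM, MCF7 3D_FBSlow and MCF7 3D_SM), MIR210HG, the host of a hypoxia-induced microRNA (4.71, 4.34, 3.36, 3.34), PPFIA4 (7.51, 6.43, 3.54, 3.29), PFKFB4 (3.48, 3.44, 3.78, 3.12), EGLN3 (2.85, 3.34, 2.99, 3.69) and ALDOC (2.70, 3.71, 5.04, 4.68). SPAG4, HIF1A-AS2 and P4HA2 followed with smallest values of 2.52, 2.48 and 2.39. In MCF7 3D_SM without replicate 2, STC1 was 2.18 and CLDN1 -5.23. The STC1 call in MCF7 3D_FBSlow ended without 2D replicate 2 (0.058) or 3 (0.057), over 0.0038 to 0.058 in all. The falls were led by CLDN1 (-2.44, -1.59, -4.20, -4.57), RBMS2, an RNA-binding protein (-1.77, -1.72, -1.32, -1.27), HES1 (-3.44, -4.76, -2.70, -1.23), ABCA1, a cholesterol exporter (-1.23, -1.61, -2.27, -1.65), and PTPN21, a phosphatase (smallest -1.09). DLC1, JDP2, SNHG12, FBXL19-AS1 and the apoptosis inhibitor BCL2 followed, each with a smallest fall between -0.996 and -0.88. The shared lower count was 111 without MCF7 2D replicate 1, 112 without replicate 3, and 233 without MCF7 3D_SM replicate 2.

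Within a line the media gave overlapping changes. In H460, 1569 genes were higher and 1711 lower in both media (753 and 771 if independent) and 435 went opposite ways (1524), and in MCF7 1578 and 1500 (671 and 700) with 420 opposite (1371). Both comparisons use the same 2D libraries, which alone gives simulated unchanged genes a correlation across genes of 0.539 in H460 and 0.483 in MCF7, against 0.645 and 0.581 measured. In 20 such simulations 0 and 0.1 genes on average were called higher in both media. The measured covariances of 0.481 and 0.449 exceed the simulated 0.033 and 0.034. Between the lines, 3D_FBSlow against 2D gave 758 genes higher in both, 566 lower in both and 1756 opposite (736, 706 and 1446 if independent), with r = -0.016 across genes. For 3D_SM against 2D these were 981, 807 and 795 (553, 589 and 1142), with r = 0.178.

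The difference between the lines was tested directly, as the log2 fold change in MCF7 minus that in H460, over 15856 genes and all 18 libraries. CPM in this part come from the scaling of all 18 libraries together and so differ slightly from those above. For 3D_FBSlow against 2D, 16 of 37 lists were called, and ATF4 targets differed in full: 21 of 21 were higher in MCF7 and 0 lower, mean 2.96, adjusted p 6.2e-43 or 1.0e-05. GDF15 went from 13.4 to 83.8 CPM in MCF7 and from 64.9 to 2.95 in H460 (difference 7.13 ± 0.35, FDR 2.1e-10). The other called differences that hold with an estimated correlation were ER stress (17 of 20 were higher in MCF7 and 0 lower, mean 1.13, adjusted p 1.7e-11 or 0.029), glutamine and amino acid use (10 of 15 were higher in MCF7 and 0 lower, mean 1.42, adjusted p 1.7e-10 or 0.025) and p53 targets (12 of 22 were higher in MCF7 and 2 lower, mean 0.87, adjusted p 4.8e-05 or 0.028). Both of the last lists lean on members they share with the ATF4 list. Without SESN2 and GDF15 the p53 difference was 0.44 (0.028 or 0.16), and without ASNS, GPT2 and SLC7A11 that of glutamine and amino acid use was 1.09 (5.0e-05 or 0.075). Hypoxia (mean 1.48, adjusted p 1.5e-09 or 0.0541) and glycolysis genes (1.30, 2.2e-09 or 0.05) were raised more in MCF7, as were ALDOC (2.33 ± 0.19, FDR 4.8e-08) and ENO2 (1.99 ± 0.42, FDR 0.0013). EGF and FGF genes differed by a mean of 1.81 (adjusted p 2.2e-06 or 0.13). The largest single differences toward MCF7, after GDF15, were FAM129A, a translation regulator that fell in H460 (551 to 22.5 CPM) and rose in MCF7 (2.88 to 15.3), ANKRD37, UNC5B and KRT15. Toward H460 they were HMCN1, a matrix protein (3.64 to 42.7 CPM in H460 and 47.6 to 6.25 in MCF7), and genes with a group at 0 or 1 counts, for which levels are given instead of a fold: FAM160A1 (0 to 2.36 in H460, 66.0 to 96.5 in MCF7), CA9 (0 to 22.3, 0.481 to 9.06), ANO1 (2.27 to 7.23, 0.183 to 0) and VIT (7.08 to 44.6, 0.326 to 0.0274). In all 6958 genes differed, 3513 toward MCF7 and 3445 toward H460.

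**Figure D3:**
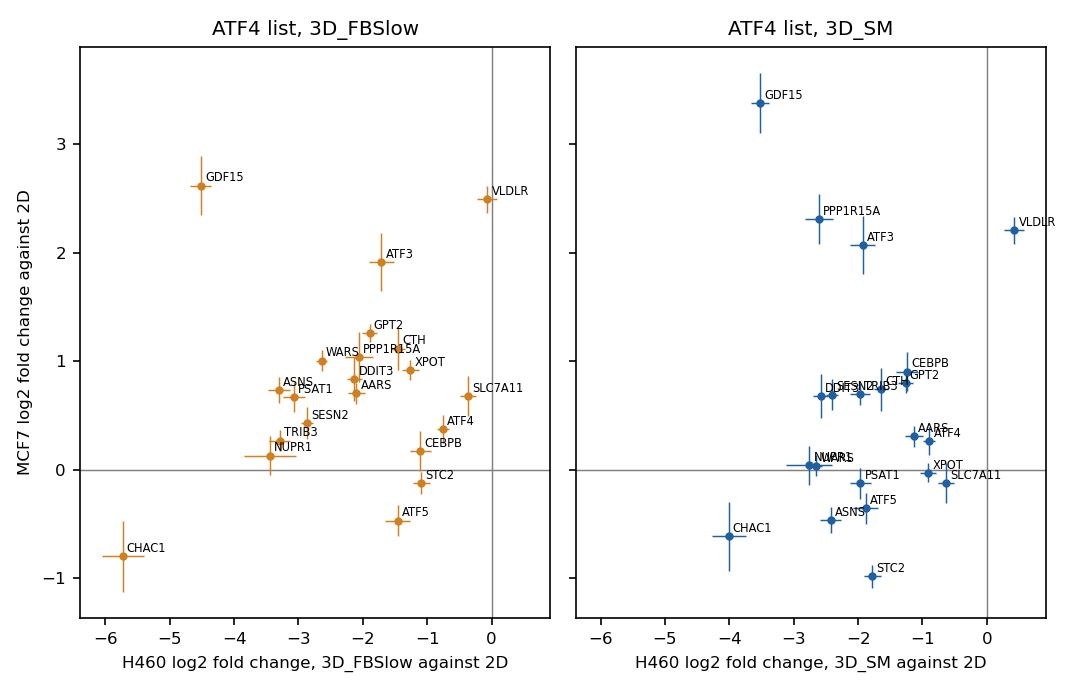
Log2 fold change of each measured member of the ATF4 integrated stress response list against 2D in H460 (horizontal) and in MCF7 (vertical), with error bars for the SE, in 3D_FBSlow and in 3D_SM. Of 21 members 20 fell in H460 in each medium, and 16 and 11 rose in MCF7.

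For 3D_SM against 2D, 17 lists were called. ATF4 targets again differed (20 of 21 were higher in MCF7 and 0 lower, mean 2.43, adjusted p 2.4e-39 or 3.5e-05), as did EGF and FGF early response genes (20 of 25 were higher in MCF7 and 1 lower, mean 2.56, adjusted p 6.8e-21 or 0.0079) and p53 targets (11 of 22 were higher in MCF7 and 3 lower, mean 0.98, adjusted p 6.1e-08 or 0.0038, and 0.59, 0.000999 or 0.0474 without SESN2 and GDF15). Luminal markers were called as lower in MCF7 with a median of 0.08 and a mean of -0.42 (adjusted p 0.004 or 0.0474), the one called list whose median and test differ in sign, and the call ended on TPM (0.111 to 0.39). Cholesterol genes rose less in MCF7 (mean -1.31, adjusted p 4.3e-11 or 0.25). ALDOC (0.92 ± 0.19, FDR 0.0012) and ENO2 (1.85 ± 0.42, FDR 0.0033) rose more. Among single genes, LAMC2, a laminin chain, went from 0.336 to 25.2 CPM in MCF7 and from 14.7 to 6.84 in H460 (7.28 ± 1.17, FDR 3.7e-04), followed by GJA1 and KRT81. SULF1 went from 531 to 5.86 in MCF7 and 0.174 to 0.348 in H460 (-7.16 ± 0.60, FDR 8.9e-08), then ATRNL1. LAMC2 differed by 5.40 without MCF7 3D_SM replicate 2, and SULF1 by -8.57 without H460 2D replicate 3. Genes with a group at 0 to 2 counts were IGFN1 (20.8 to 0.948 CPM in H460, 0.0342 to 1.21 in MCF7), ITGB6 (0.0425 to 0, 0.986 to 47.4), UGT2B15 (0 to 0.0413, 19.4 to 0.424), KLHL4 (17.1 to 30.4, 0.913 to 0) and FAM160A1 (0 to 1.51, 66.0 to 83.1). In all 5104 genes differed, 2422 toward MCF7 and 2682 toward H460.

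For 3D_SM against 3D_FBSlow, cholesterol (0 of 23 were higher in MCF7 and 23 lower, mean -1.70, adjusted p 3.8e-16 or 0.31), mitosis (0 of 28 were higher in MCF7 and 27 lower, or 0 and 28 adjusted over the list alone, mean -1.13, adjusted p 1.3e-09 or 0.36) and respiratory chain genes (0 of 43 were higher in MCF7 and 36 lower, mean -0.79, adjusted p 1.5e-07 or 0.47) rose more, or fell less, in H460. No list of the 19 called was called with an estimated correlation. ALDOC differed (-1.41 ± 0.18, FDR 1.0e-05) and ENO2 did not pass (-0.14 ± 0.40, FDR 0.81). ABCC3 went from 10.0 to 174 CPM in MCF7 and from 275 to 98.7 in H460 (5.61 ± 0.22, FDR 1.4e-11). AREG, a ligand of the EGF receptor, went from 294 to 51.0 in MCF7 and from 0.881 to 7.04 in H460 (-5.57 ± 1.15, FDR 0.0017), and ATRNL1 from 9.35 to 0.149 and from 10.8 to 12.2 (-6.03 ± 0.37, FDR 6.9e-09). AREG differed by -7.435 without MCF7 3D_SM replicate 2 and ATRNL1 by -6.80 without replicate 3. Genes with a group at 0 to 2 counts were CLCA2 (0.0958 to 0.0283 CPM in H460, 0.463 to 22.2 in MCF7), INHBA (12.9 to 9.47, 0 to 0.555), ITGB6 (0.03 to 0, 4.38 to 47.4), VIPR1 (0.108 to 0.0128, 4.19 to 49.7), UGT2B15 (0 to 0.0413, 14.3 to 0.424), KLHL4 (10.8 to 30.4, 0.339 to 0) and BNC2 (10.2 to 29, 0.137 to 0). In all 7087 genes differed, 3278 toward MCF7 and 3809 toward H460. The 3 endothelial markers tested in the differences were not called (adjusted p 0.83, 1.00 and 0.6).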

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

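Of the tests below, those on the scaling of the ATF4 list, on RNA from H460 cells or keratinocytes, on RNA composition, on each library that stood apart, without members on the ATF4 list, on 3D_SM RNA mixed in and on a wrong label were chosen after the result was seen, as were the versions of 2 correlations with no shared library and the thresholds named below.

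Each result in this part is a difference between the lines that was itself tested, as the change in MCF7 minus the change in H460. For 3D_FBSlow against 2D, 6958 genes differed, and 4 lists did so under camera with a preset and an estimated correlation: ATF4 targets (mean 2.96), glutamine and amino acid use (1.42), ER stress (1.13) and p53 targets (0.87). Without members on the ATF4 list, the glutamine and p53 lists differed by 1.09 and 0.44 and were not called with an estimated correlation (0.075 and 0.16). ALDOC differed by 2.33 and ENO2 by 1.99. The largest differences of single genes with more than 3 counts in every group were GDF15 (7.13), FAM129A (7.01), ANKRD37 (6.65), UNC5B (6.44), KRT15 (6.0, 5.385 without MCF7 3D_FBSlow replicate 1) and HMCN1 (-6.48).

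For 3D_SM against 2D, 5104 genes differed. The lists were EGF and FGF early response genes (2.56), ATF4 targets (2.43), p53 targets (0.98, or 0.59 without SESN2 and GDF15) and luminal markers (-0.42, with a median of 0.08, not called on TPM at 0.111 to 0.39). ALDOC differed by 0.92 and ENO2 by 1.85, and the largest single differences were LAMC2 (7.28), GJA1 (7.22), KRT81 (7.08), SULF1 (-7.16) and ATRNL1 (-7.13). Without MCF7 3D_SM replicate 2 LAMC2 differed by 5.40 and KRT81 by 5.84, without its replicate 3 ATRNL1 by -7.90, and without H460 2D replicate 3 SULF1 by -8.57. Between the media, 7087 genes differed, with ALDOC at -1.41, ABCC3 at 5.61, AREG at -5.57 (-7.435 without MCF7 3D_SM replicate 2) and ATRNL1 at -6.03 (-6.80 without replicate 3). Groups of 3 libraries are too small for a test of single outlying libraries within the group, and no deposited column was left unused.

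Other splits of the 6 libraries of a comparison within a line number 10, the real one included, so their share cannot fall under 0.05. The real split gave the most genes in 1 of 10 each time. In H460 the real counts were 7268, 6036 and 7180 and the highest others 0, 0 and 4. In MCF7 they were 6435, 6144 and 6144, and the highest others 0, 0 and 0. For the line differences 1 of 40 splits drawn, the real one, gave as many genes. That argues only against a chance division among cultures, as lines with the same changes were not modelled. The highest others were 3611, 2845 and 5292 against 6958, 5104 and 7087. Such large counts in other splits point to a structure of the samples, since these splits exchange libraries between the cultures of each line and can leave the cultures of 1 line apart. For genes shared by all 4 comparisons, 1 of 40 splits, the real one, gave as many as 334 higher and 172 lower, and the highest others gave 0 and 0. In each of the other splits at least 1 of the 4 comparisons called 0 genes, so these splits say nothing about sharing. If the lines were independent, 155 and 152 would be shared, and for the lower genes chance overlap is not excluded (Fisher's exact p 0.0681).

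ATF4 targets fell in H460 in both spheroid media and rose in MCF7, by 16 of 21 members in 3D_FBSlow and 11 in 3D_SM, a rise that was not called with an estimated correlation (adjusted p 0.0547 and 0.26). Scaling of the libraries is argued against as the whole cause: the mean difference between the lines was 2.96 and 2.43, and its lowest value under RLE scaling, library totals or log2(TPM + 1) was 2.05. The 2D medium, RPMI for H460 and DMEM for MCF7, stays open, because line and 2D medium cannot be told apart. The list stood 1.53 log2 CPM higher in H460 than in MCF7 in 2D and 1.26 and 0.77 lower in 3D_FBSlow and 3D_SM, so a state of the H460 monolayer may account for part of the difference. A difference between the lines in how they answer to growth in 3D stays open too, and was not tested apart from the medium.

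MCF7 3D_SM replicate 2 stood apart. A test of 1 library against 2, picked because it stood apart, only describes it, and put the NF-kB list first. RNA from H460 cells is argued against, since 176 genes of H460 that the other MCF7 libraries lack reached together 0.0579% of their summed H460 level. A first version, the median over those genes, gave 0% and was replaced because single genes are at the floor. RNA from keratinocytes is argued against: KRT5 and KRT14, among their most abundant transcripts, had 4 and 6 counts beside 344 for KRT16 and 186 for KRT6A, together 1.89% of the latter. The leukocyte genes PTPRC, LYZ and TYROBP had 0 counts each, beside 707 for CD68. A stronger form of the change seen in the other 3D_SM libraries stays open. Its correlation across 11513 genes was 0.075, under the bound of 0.1 set against it, but replicates 1 and 3 enter both terms with opposite sign, which pulls it down. With no shared library it was 0.188, between the bounds of 0.1 and 0.3, so the test as designed decides nothing. The RNA composition of the library, with 9.57% ribosomal RNA against 3.69 and 7.23%, stays open: the difference between the libraries with most and least ribosomal RNA of the 5 other groups correlated with its deviation at -0.066 to 0.374.

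H460 3D_FBSlow replicate 3 stood apart, and a test with the same limit put cholesterol, mitosis and histone genes first. RNA of a 3D_SM library mixed in is argued against as the whole cause, since mixing alone would move all genes by 1 share. The 49 genes at least 4 times higher in 3D_FBSlow moved by a median of 59.3% towards 3D_SM and the 56 higher in 3D_SM by 17.5%, a difference of 41.8 points. A two-sided permutation test gave p 1e-04, the smallest the permutations run can give. With an earlier threshold of 8 times (4 and 6 genes) the difference was 28.6 and p 0.27, which decided nothing. A wrong label is argued against by the median share of 25.3% with an upper quartile of 61.7%, where a 3D_SM library would be near 100%. An earlier form, the mean correlation with replicates 1 and 2 (0.97) and with 3D_SM (0.96), was replaced as too close to saturation. Whether the changes only went less far from 2D stays open. The correlation of replicate 3 minus replicate 1 with replicate 2 minus 2D was -0.373 across 11286 genes, but what replicates 1 and 2 share enters it with opposite signs and makes it negative. With 3D_SM minus 2D as the second term, which has no library in common with the first, it was 0.187, so the test as designed decides nothing. The RNA composition of the library, with 0.772% ribosomal RNA against 4.04 and 3.96%, stays open too, at correlations of -0.304 to 0.471 in the same test. Replicates 1 and 2 may be the unusual pair, since they differ by little more than sampling.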

How the results depend on the processing

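The fits with replicates 1 and 2 of H460 3D_FBSlow summed, and with both libraries that stand apart left out, were chosen after the data were seen.

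The 9 counts of genes changed stayed within 1.5 times their value under every alternative, with these exceptions. At least 2-fold, fewer genes pass by construction: 2064, 1494 and 1652 in H460 (3D_FBSlow against 2D, 3D_SM against 2D, 3D_SM against 3D_FBSlow), 1837, 2023 and 1745 in MCF7, and 3545, 2305 and 3293 for the line differences. On log2(TPM + 1) without a filter, MCF7 3D_SM against 3D_FBSlow gave 3866, and the cause was not tested. Leaving out 1 library gave 5969 to 8701, 4503 to 5423 and 5467 to 9118 genes in H460, 4462 to 5318, 4478 to 6889 and 4743 to 7236 in MCF7, and 5997 to 7520, 4272 to 5974 and 5913 to 7748 for the line differences. Where that leaves 2 libraries in a group, the fit pools the spread over groups. The 2 highest H460 values are those without 3D_FBSlow replicate 3. With its replicates 1 and 2 summed, the counts it enters were 6361 and 5818, and 6258 and 6137 for the line differences.

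The 334 genes higher in all 4 comparisons became 74 at 2-fold, 222 with library totals only, 179 on log2(TPM + 1), 189 on log2(TPM + 0.1) and 166 without a filter there, and 255 to 396 without 1 library. The 172 lower became 13, 320, 107, 91 and 96 in those settings, 265 with both libraries that stand apart left out, and 111 to 233 without 1 library. Of the 320, 166 are among the 172. Library totals shift the median log2 fold change of all genes in MCF7 by -0.22 (3D_FBSlow) and -0.18 (3D_SM), and the line differences by -0.18 and -0.18, which makes more genes lower. Otherwise the cause was not tested.

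The split into higher and lower also moved. With library totals 27.3% and 31.8% of the MCF7 calls against 2D were higher, and 39.7% and 35.3% for the line differences. On log2(TPM + 1) it was 36.2% in MCF7 3D_FBSlow against 2D and 62.7% in H460 3D_SM against 3D_FBSlow.

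The replicate block gave 6909, 5669 and 6776 genes in H460, 5619, 5385 and 5381 in MCF7 and 6518, 4652 and 6600 for the line differences. Deviations of same-numbered libraries from their group means correlated at -0.383 to 0.229 in H460 and -0.411 to 0.121 in MCF7 (medians -0.054 and -0.048, against 0.042 and 0.0275 for different numbers), so the numbers do not pair libraries.

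For 1090 named-gene results, 20712 alternatives left calls as they were in 20212, ended a call in 412, made one in 74 and turned a called direction in 14. For 321 list results these were 6375 of 6809, 240 (130 from the estimated correlation), 194 and 0. Turns called in neither fit were not counted. DESeq2 gave MMP1, LOX, CLIP4, CD68, LRRC15, S100A9, SBSN, LAMC2 and AREG no adjusted p in comparisons where edgeR called them. Folds on log2(TPM + 1) are smaller by construction for low genes. The line difference turned to 0.097 (3D_FBSlow) and 0.119 (3D_SM) for FAM160A1, to -0.28 for ESR1 (3D_FBSlow) and to 0.018 for COL3A1 (3D_SM) on log2(TPM + 1) with and without a filter, and to 0.218 for CD19 (3D_FBSlow) without one. Between the media EMCN turned to 0.478 on log2(TPM + 1), with and without a filter, and 0.348 on log2(TPM + 0.1). CD68 in MCF7 3D_SM against 3D_FBSlow, not called at 0.82, was -0.73 without 3D_SM replicate 2 and with both libraries that stand apart left out, and -0.73 to 1.245 without 1 library. The cause was not tested.

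Simulations with few changed genes, unlike the data, recovered 49.3% (H460) and 25.4% (MCF7) of 1.5-fold changes. Smaller changes may be missed.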
